A study of Mus musculus with 4 samples.

How the data were processed

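The series holds 4 samples of mouse lung mesenchyme, 2 controls and 2 Sin3a conditional knockouts, prepared with the 10x Genomics 3′ chemistry version that the labels' protocols name (v3.1). The deposited matrix holds whole UMI counts per gene and barcode, per the file headers and the values themselves. It is a single unfiltered table of 31053 genes and 27179520 barcodes, 6794880 for each of 4 barcode suffixes, with 138446117 entries. Per the submitters' processing notes, Cell Ranger 6.1.1, R 4.0.2, Seurat 4.0.5 and the mm10 genome were used; the file header names Cell Ranger 4.0.0, and the difference was left open. The protocol also describes an RNA extraction from sorted mesenchymal cells, while the source label names whole lung.

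No label, header or barcode ties a suffix to a sample, so no cell was given to a group. The edgeR comparison of control with knockout cells was not run, and no p-value is reported. Values are given per library, numbered by suffix, with exact Poisson intervals for CPM and exact Clopper-Pearson intervals for shares, at a confidence level of 95%. These cover counting error alone. Libraries held between 94221345 and 120611662 UMIs, and those of mesenchymal cells give an interval of about 1 CPM to either side of a gene at 30 CPM such as Sin3a.

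Barcodes with at least 1000 UMIs, at least 500 genes and under 10% mitochondrial UMIs were kept as cells. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.06. The caller marked 11 of the cells, or 0.0159% to 0.0533% of a library, and so did not work on these data; the cells it marked were removed, and an alternative that removes the highest 6% of doublet scores in each library was added. The 29912 remaining cells were scaled to 10000 counts and log transformed. Clustering used 2000 variable genes without the genes of the programme lists (sex-linked genes among them) and without ribosomal, mitochondrial and haemoglobin genes, 30 principal components, 15 neighbours and Leiden resolution 1 (igraph 0.11.9, 2 iterations, seed 7), with no integration of libraries, and gave 24 clusters. A cluster took the name of the marker list with the highest mean z-scored expression among 12 lists, less any marker that is also a programme gene. It stayed unnamed with under 3 of those markers in over 10% of its cells, with more leading genes of another list than of its own among its top 10 by fold, or with a low UMI count and no own marker among them. The checks of leading genes used the full lists, programme genes included. Clusters scoring highest on 1 of 6 mesenchymal lists, with at least 3 of its markers detected, counted as mesenchymal, named or not, and a class called X-like means resemblance by these markers only.

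UMIs were summed per library and class and scaled to CPM. The level of a list is the summed CPM of its genes. Within each library, the CPM of a class was divided by that of all other mesenchymal cells. A gene was called higher at a ratio of at least 2 and at least 50 CPM in the class, and lower at a ratio of at most 0.5 and at least 50 CPM in the other cells, in every library with at least 50 cells of the class. A level under 3 counts was set to 3 counts in ratios. The text names, per class, the 4 highest and 2 lowest called genes by the ratio nearest 1 over libraries, the 20 genes with the largest ratio of highest to lowest library apart from sex-linked, haemoglobin and mitochondrial genes, Sin3a and Sin3b, and the sex-linked genes; other members of lists are named as examples chosen after their values were seen. Of 413 distinct genes on the 18 programme lists, 413 were found in the files, 3 of them under older symbols matched by Ensembl identifier. Positions are from GENCODE M21 on GRCm38.

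The calling rule was tested on simulated counts made from the pericyte-like comparison, with 200 of 3443 genes changed. It recovered 0 of 50 genes changed 1.5-fold, 43 of 50 changed 3-fold, 46 of 50 changed 4-fold and 47 of 50 changed 8-fold, and called 0 of 3243 unchanged genes. The results at 1.5-fold and for unchanged genes follow largely from the required ratio of 2. The simulated spread between libraries was a set standard deviation of 0.15 on the natural log scale, not taken from the data. Cycling was measured as cells with at least 2 UMIs of the G2 and M phase list after thinning to 2000 UMIs. Alternatives changed the UMI minimum (500 or 3000), the mitochondrial limit (5%), the removal of doublets, the resolution (0.5 or 2), the naming, the libraries included, the CPM minimum (10 or 200), the scaling (TMM factors from edgeR 4.0.16) and the thinning. Computations ran in Python 3.11.15 and R 4.3.3 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.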

Results

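Lung mesenchyme of mouse embryos at embryonic day 16 was profiled by droplet single-cell RNA sequencing, which counts transcripts of single cells from their 3′ ends with unique molecular identifiers (UMIs). The labels describe 2 control samples, heterozygous for a conditional Sin3a allele, and 2 conditional knockout samples with both alleles conditional. Cre was under a doxycycline-inducible driver with a Tbx4 element, active in lung mesenchyme, and doxycycline was given to the dams from embryonic day 12. The question put by the design is how loss of Sin3a, the scaffold protein of a histone deacetylase complex that represses transcription, changes the mesenchyme. The deposited matrix joins 4 libraries, told apart by the number at the end of each cell barcode, and neither a label nor a file ties a number to a sample. The libraries therefore stay unassigned, control and knockout were not compared, and each library is given by itself as libraries 1 to 4. Library totals were 119335220, 120611662, 118136206 and 94221345 UMIs. After filtering, 8098, 8004, 7502 and 6308 cells remained, with a median of 13062, 13432, 14094.5 and 13872 UMIs per cell. Intervals are exact 95% Poisson intervals for CPM (counts scaled to the library's total in that class of cells) and exact Clopper-Pearson intervals for shares of cells. They cover counting error only, and no value here has a replicate error.

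Sin3a transcripts were present at nearly the same low level in mesenchymal cells of every library. Sin3a (ENSMUSG00000042557) lies on chromosome 9 from 57072040 to 57128366 in GRCm38, on the plus strand. Its level was 28.4 CPM (27.4 to 29.4) in library 1, 29.3 CPM (28.3 to 30.3) in library 2, 27.7 CPM (26.7 to 28.7) in library 3 and 30.5 CPM (29.3 to 31.7) in library 4, so that the highest was 1.1 times the lowest. With TMM scaling the levels in libraries 1 to 4 were 26.4, 28.3, 29.3 and 32.0 CPM, a wider range with library 1 lowest. The 3′ tags read the end of the transcript, and the part of the gene that recombination removes is not given in the sources used here. The level thus checks no label.

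Genes of the SIN3 complex list spanned from 1.07 times (Sap18) to 3.1 times (Mnt) between the lowest and the highest library, against 1.1 times for Sin3a. Sin3b (ENSMUSG00000031622; chromosome 8, 72723285 to 72758201), the paralogous scaffold, was at 151 CPM (149 to 154), 152 CPM (150 to 154), 219 CPM (216 to 221) and 229 CPM (226 to 232) in libraries 1 to 4. The histone deacetylases of the complex lay close together, with Hdac1 at 101, 101, 94.8 and 92.9 CPM and Hdac2 at 160, 170, 152 and 153 CPM. Of the 26 genes on the list, 5 had a highest library at least 2 times the lowest. These were the corepressor subunits Sap30 (35, 40.8, 93.8 and 93.8 CPM) and Sap30l (75.4, 69.3, 133 and 142 CPM), Ing2, which reads methylated histone H3 (50.1, 49.2, 115 and 116 CPM), and the MAX partners Mnt (15.2, 13.7, 42.7 and 40.9 CPM) and Mxd1 (12.7, 10.8, 24.4 and 25.1 CPM). The summed list stood at 2220, 2210, 2780 and 2800 CPM.

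**Figure D1:**
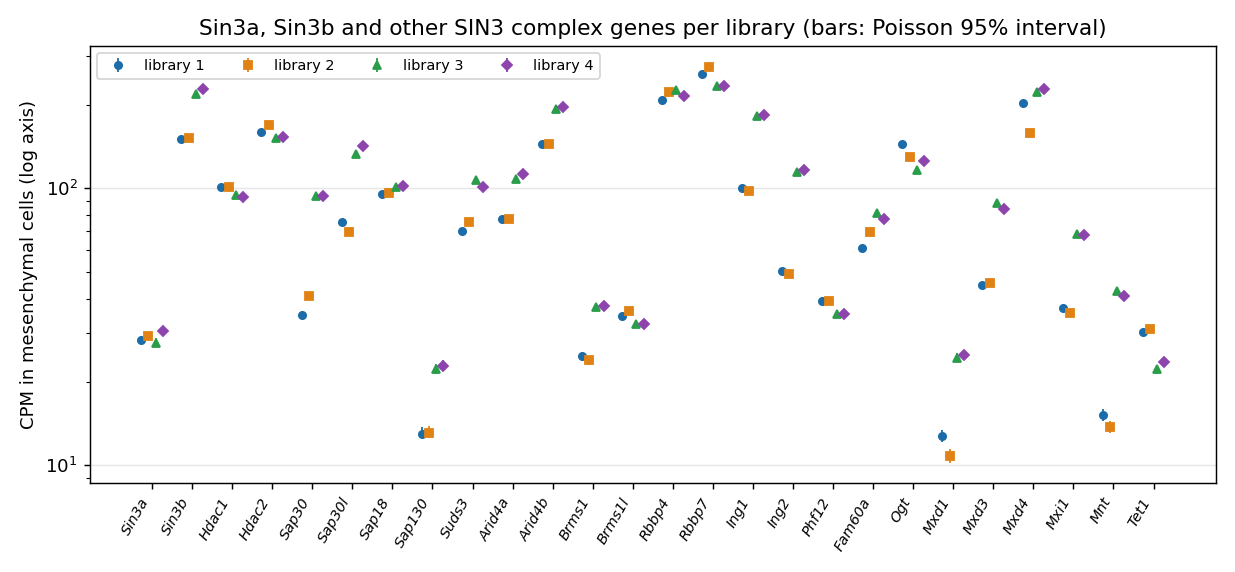
CPM of each SIN3 complex gene over all mesenchymal cells (vertical log axis), 1 point per library, bars giving the exact 95% Poisson interval. The 4 points of Sin3a lie between 27.7 and 30.5 CPM, whereas those of Sap30 range from 35 to 93.8 CPM; Fam60a is the name the files use for Sinhcaf.

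Most cells resembled mesenchyme by their markers; the protocol names a sort for mesenchymal cells, which can set these shares, while the tissue label reads as whole lung. Of all cells, 94.2% (93.6 to 94.7), 96.3% (95.9 to 96.7), 96.1% (95.7 to 96.5) and 91.4% (90.7 to 92.1) in libraries 1 to 4 lay in mesenchymal clusters. Immune-like cells made up 0.889%, 0.637%, 1.27% and 1.52%, mesothelial-like cells 0.617%, 0.487%, 0.213% and 0.476%, endothelial-like cells 0.642%, 0.312%, 0.307% and 0.238%, and epithelial-like cells 0.309%, 0.075%, 0.173% and 0.254%. No cluster was named erythroid-like or neural-like, which sets no limit on such cells. An unnamed cluster of shallow barcodes, with a median of 1606 UMIs, scored highest on the neural list without 3 detected markers of it and held 3.37%, 2.19%, 1.92% and 6.1% of the cells. The mesenchymal share depended on the naming of clusters: its median over libraries was 95.1%, 80.8% when each library was clustered alone and 78.1% by the highest marker score per cell, which also gave medians of 5.22% mesothelial, 3.28% endothelial and 1.26% epithelial cells.

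Within the mesenchyme, pericyte-like cells, which carry markers of vascular mural cells such as Notch3, formed a single cluster with 7.04% (6.49 to 7.62), 4.42% (3.98 to 4.9), 3.31% (2.91 to 3.74) and 3.04% (2.63 to 3.5) of the cells in libraries 1 to 4. Smooth muscle-like cells made up 12% (11.3 to 12.7), 10.2% (9.58 to 10.9), 0.746% (0.564 to 0.968) and 0.745% (0.548 to 0.99). Distal interstitial fibroblast-like cells made up 49.6% (48.5 to 50.7), 49.2% (48.1 to 50.3), 68.8% (67.7 to 69.8) and 66.5% (65.3 to 67.6). No cluster was named myofibroblast-like, but clusters 6 and 19 scored highest on that list and stayed unnamed, so this sets no limit on such cells. Different clusters held these classes in different libraries: distal interstitial fibroblast-like cells of libraries 1 and 2 lay mostly in clusters 1, 2, 4 and 5, and those of libraries 3 and 4 in clusters 14, 18, 22 and 23. The mean z-score of the distal markers was 0.58, 0.41, 0.35 and 1.42 in clusters 1, 2, 4 and 5. It was 1.07, 0.31, 0.12 and 0.17 in clusters 14, 18, 22 and 23, so several of these clusters resembled the class only weakly. Clusters 18, 22 and 23 held 1559, 1005 and 455 of the 5159 cells of the class in library 3. Smooth muscle-like cells of libraries 1 and 2 lay mostly in clusters 3 and 12, and those of library 3 and library 4 in clusters 9 and 12. Unnamed mesenchymal clusters were described by the marker list on which they scored highest, a grouping chosen after seeing the data. On that grouping, clusters scoring highest on the distal list held 59.7%, 64.1%, 83.0% and 79.2% of the cells, and clusters scoring highest on the smooth muscle or myofibroblast list, called contractile-scoring, held 20.4%, 21.4%, 7.02% and 6.58%. The contractile-scoring cells of libraries 1 and 2 lay mostly in clusters 3, 6 and 12, and those of libraries 3 and 4 mostly in cluster 19 (464 of 527 and 356 of 415 cells), which held 3 cells of library 1 and 0 of library 2. Only cluster 10 scored highest on the proximal and adventitial fibroblast list, and it held 7.08%, 6.42%, 2.8% and 2.55%. By the highest marker score per cell, the median over libraries went from 71.7% to 37.5% for distal-scoring and from 3.86% to 7.1% for pericyte-like cells. Pericyte-like cells made up 6.16% with each library clustered alone. Without library 4 they made up 5.86%, against a median of 4.42% for the remaining libraries in the main clustering. The contractile-scoring median over all libraries was 13.7%. It was 6.13% without library 1 and 8.05% without library 2, against 7.02% for the remaining libraries in the main clustering. Without library 3 it was 13.1% and without library 4 13.4%, against 20.4% for the remaining libraries.

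**Figure D2:**
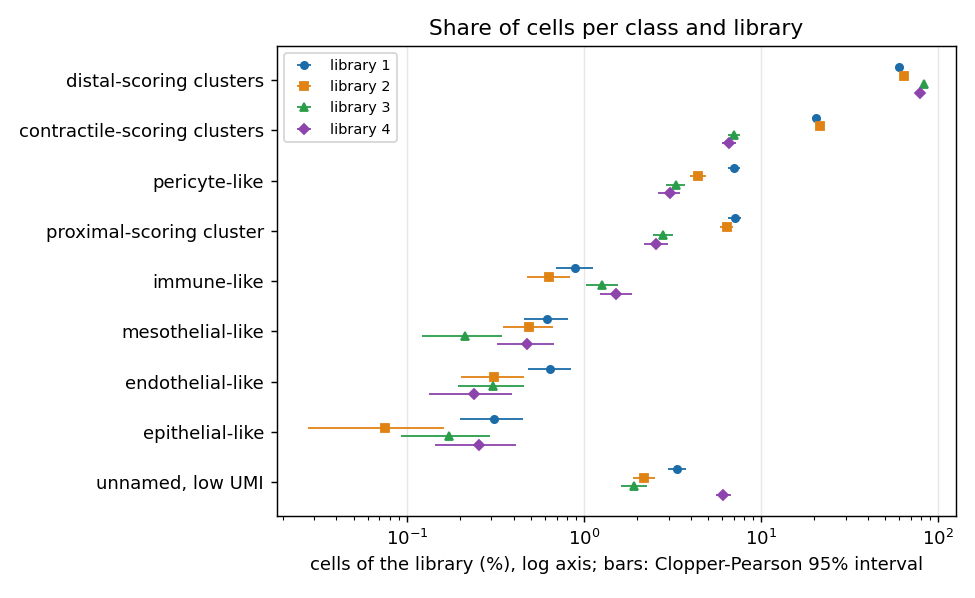
Share of each library's cells (horizontal log axis, percent) in each class or set of clusters, 1 point per library, with exact Clopper-Pearson 95% intervals. Distal-scoring clusters held between 59.7% and 83.0% of the cells, contractile-scoring clusters between 6.58% and 21.4%, and immune-like, mesothelial-like, endothelial-like and epithelial-like cells under 2% each.

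Pericyte-like cells differed from the other mesenchymal cells in genes of the PDGF, Notch and VEGF, matrix, lipid handling and WNT lists, among others. A gene was called when its CPM in the class was at least 2 times, or at most 0.5 times, that in the other mesenchymal cells in every library holding at least 50 cells of the class. Of 413 programme genes, 11 were called higher and 25 lower in pericyte-like cells. Periostin (Postn) was 56 to 242 times higher, the chemokine gene Ccl2 31.3 to 81.8 times, the Notch target Heyl 13.8 to 31.4 times and the PDGF receptor gene Pdgfrb 11.9 to 19.5 times. Postn, Pdgfrb and Notch3 also stand on the marker list of the class, although none of them was used to cluster or score it. Postn, a leading gene of the cluster, did count as an own marker in the check of its name. A gene counted as measured if it reached 50 CPM in the class or in the other cells in every library. A gene can thus enter only because it is high on the side where it is called. Shares of measured genes that were called are therefore set in part by this rule, here and below. Of the 11 measured genes of the PDGF, Notch and VEGF list, 4 were higher (Heyl, Pdgfrb, Notch1 and Notch3) and 4 lower. The fibrillar and basement membrane matrix list gave 3 higher, namely Postn and the collagen IV chains Col4a1 and Col4a2, and 9 lower, among 30 measured. Of 15 lipid handling genes, 5 were measured and all 5 were called, Fabp5 and Hilpda higher and Apoe, Cebpb and Plin2 lower. Of 24 WNT genes, 3 were measured, and all 3 (Wnt2, Tcf7 and Nkd1) were lower. The hedgehog target Hhip was 12.3 to 28.5 times lower, and the epithelium-directed ligand gene Wnt2 11.9 to 17.1 times lower.

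In the contractile-scoring clusters 11 programme genes were called higher and 7 lower than in the other mesenchymal cells. These are not a named class: clusters 6 and 19 stayed unnamed because markers of another list outnumbered their own among their 10 leading genes, and different clusters hold the set in different libraries. In cluster 6 the marker was Ramp2, of the endothelial list. In cluster 19 they were the haemoglobin genes Hbb-bs, Hba-a1 and Hbb-bt, of the erythroid list, and Lgr6, of the smooth muscle list. No myofibroblast marker was among its leading genes. Haemoglobin genes made up 303, 67.5, 588 and 756 CPM of the free RNA in libraries 1 to 4. Among the leading genes that remain without haemoglobin, Lgr6 would still outnumber the cluster's own markers. Whether free RNA kept cluster 19 unnamed was not tested. Fgf18, which encodes a fibroblast growth factor, was 52.5 to 83.1 times higher than in the other mesenchymal cells, the matricellular gene Ctgf 10.2 to 13.9 times, Igf1 8.64 to 9.66 times and the FGF feedback inhibitor Spry1 5.28 to 7.17 times. Of those called higher, Fgf18, Hhip, Nkd1, Pdgfra and Wnt5a also stand on the myofibroblast marker list, although none was used to cluster or score the set. Of 7 measured genes of the sonic hedgehog list, Hhip and Foxf1 were called higher and none lower. Vegfd was 5.02 to 8.99 times lower and Cebpb 3.32 to 5.59 times lower, and 3 of 4 measured lipid handling genes were called lower (Cebpb, Apoe and Plin2). The class named smooth muscle-like could be tested only in libraries 1, 2 and 3, since library 4 held 47 such cells. There 12 genes were called higher, led by Ctgf (11.6 to 44 times), the WNT-associated receptor gene Lgr6 (11.2 to 73.4 times), Ltbp2 (7.76 to 11.4 times) and Spry1 (5.67 to 6.68 times), and 9 lower, led by Vegfd (10.1 to 12.5 times) and Wnt2 (7.39 to 12.5 times). Lgr6 also stands on the smooth muscle marker list, although it was not used to cluster or score the class. Without library 3, 21 genes were called higher in smooth muscle-like cells, and without library 2, 18 were called higher in the contractile-scoring clusters. In smooth muscle-like cells a minimum of 3000 UMIs per cell gave 30 higher and 70 lower, removal of the highest 6% of doublet scores 35 and 71, and resolution 2 gave 25 lower.

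In cluster 10, 16 programme genes were called higher and 20 lower. This cluster scored highest on the proximal and adventitial list but stayed unnamed, since its 10 leading genes held Rgs5, a marker of another list, and none of its own. Of the 16 called higher, 11 belonged to the 32 measured genes of the matrix list. Elastin (Eln) was 7.93 to 22.1 times higher and fibulin 5 (Fbln5) 12.3 to 25.8 times. The insulin-like growth factor binding protein genes Igfbp5 and Igfbp7 were 12.9 to 25.2 and 6.29 to 21.9 times higher. Of the 20 genes called lower, 14 were among the 34 measured genes of the G2 and M phase list, Top2a and Mki67 among them. The other mesenchymal cells included clusters led by mitotic genes (4 and 23) and by histone genes (2 and 18). How far this makeup contributes to these calls was not tested. Wnt2 was 5.25 to 11.6 times lower and the WNT effector gene Tcf7 3.74 to 7.38 times lower. Without library 3, 34 genes were called lower, and 10 were with a minimum of 3000 UMIs and 11 at resolution 2. Only 3 genes were called higher without the highest 6% of doublet scores, and with doublets kept no cluster scored highest on that list.

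**Figure D3:**
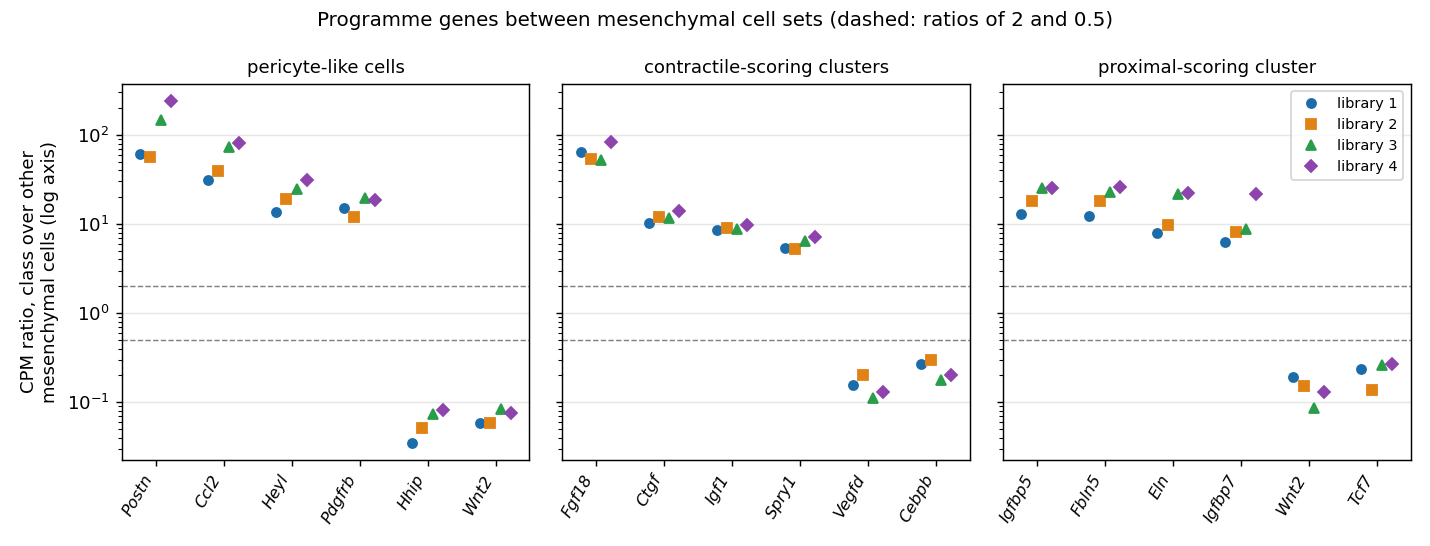
Ratio of CPM in a set of cells to CPM in all other mesenchymal cells of the same library (vertical log axis) for the 4 highest and 2 lowest called programme genes, 1 point per library. All points of Postn lie at 56 or above and all points of Hhip at 0.0814 or below in pericyte-like cells, and dashed lines mark the ratios of 2 and 0.5 that a call needs.

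Distal interstitial fibroblast-like cells showed 8 genes called higher, all from the G2 and M phase list, and 9 lower. Top2a was 2.27 to 3.37 times, Cenpf 2.17 to 4.94 times, Kif20b 2.16 to 3.53 times and Hmmr 2.1 to 5.48 times the level in the other mesenchymal cells. The class included clusters led by mitotic genes (4 and 23) and by histone genes (2 and 18), while the distal-scoring clusters 7, 11 and 21 stayed unnamed and counted among the other cells. The makeup of the class may thus contribute to these calls, and how far it does was not tested. Postn was 15.7 to 90.2 times lower and Ctgf 11.6 to 18.5 times lower, and the matrix list gave 5 lower among 31 measured. Among these, Lum and Dcn are markers of the proximal and adventitial list. Both were leading genes of clusters 7 and 21, and Lum was one of cluster 11. Such leading genes kept those clusters unnamed and so among the other cells. The calls of Lum and Dcn were thus set in part by the naming. The counts depended on the settings, and the cause was not tested. No gene was called higher at a clustering resolution of 0.5, 34 were at a resolution of 2, 20 with a minimum of 3000 UMIs, 31 without library 1, and 2 either with doublets kept or without the highest 6% of doublet scores. Keeping doublets added only 11 cells, so the calls were sensitive to a very small change of the cells clustered. The 9 called lower became 2 at a resolution of 0.5, 4 without the highest doublet scores, and 5 either with 3000 UMIs or at a resolution of 2.

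The programme lists spanned different ranges over the 4 libraries, and 8 of 18 lists had a summed CPM in the highest library at least 1.5 times that in the lowest; the sonic hedgehog list fell just short before rounding. The 8 include the embryo sex list and the neuronal and germline lists, which summed to at most 17.2 and 7.25 CPM. The fibrillar and basement membrane matrix list summed to 14500, 11400, 8990 and 9800 CPM in libraries 1 to 4, the lipid handling list to 1320, 970, 682 and 840 CPM, and the senescence associated list to 248, 229, 111 and 115 CPM. Within the last, Timp1, an inhibitor of matrix metalloproteinases, was at 31.3, 32.7, 1.76 and 2.22 CPM and Igfbp7 at 44.7, 28, 8.83 and 10.4 CPM. The cell cycle inhibitor gene Cdkn1a, on that list and on the p53 list, was at 8.92, 9.14, 7.52 and 8.77 CPM. This pooled level hid differences between classes. Cdkn1a was at 1.5, 7.59, 25.1 and 26.7 CPM in pericyte-like cells and 14.9, 12.1, 20.2 and 30.2 CPM in contractile-scoring clusters. It was at 14.8, 20.4, 12.1 and 1.62 CPM in cluster 10 and 6.95, 7.35, 5.51 and 6.46 CPM in distal-scoring clusters. In cluster 10 the library 4 value rests on 3 counts (interval 0.334 to 4.73 CPM) and that of library 3 on 28 counts. The p53 target list summed to 1350, 1240, 1430 and 1440 CPM, with the apoptosis gene Bax at 206, 210, 324 and 324 CPM and Ccng1 at 17.4, 16.8, 36.4 and 36.7 CPM, but Btg2 at 481, 396, 275 and 278 CPM and Ddit4 at 21, 19.8, 7.4 and 7.26 CPM. The sonic hedgehog list summed to 1300, 1200, 865 and 883 CPM, and its members spanned from 1.08 times for Gli1 (33, 33.7, 34.7 and 35.6 CPM) and 1.17 times for Ptch1 (295, 251, 251 and 263 CPM) to 2.53 times for Hhip (188, 113, 74.2 and 79.1 CPM), 8.98 times for the cyclin gene Ccnd1 (17.5, 25.7, 3.02 and 2.86 CPM) and 11.2 times for Ccnd2. The PDGF, Notch and VEGF list summed to 1180, 931, 727 and 757 CPM, and the list of dissociation and stress genes to 4740, 5100, 3590 and 3370 CPM. The lists of WNT (733, 733, 610 and 583 CPM), FGF (504, 387, 412 and 438 CPM), BMP and TGF beta (1690, 1430, 1220 and 1300 CPM), retinoid (784, 881, 672 and 705 CPM) and interferon genes (442, 378, 345 and 372 CPM) spanned under 1.5 times by summed CPM. The order of the lists depended on the measure. By the median of log2 CPM over a list's genes, the matrix list spanned 1.19 times and the lipid handling list 1.26 times, against 2.19 times for WNT, 1.94 times for retinoid and 2.36 times for interferon genes, and with classes weighted equally the PDGF, Notch and VEGF list spanned 1.18 times and the retinoid list 1.53 times. No gene of the neuronal or the germline list passed 10 CPM in any library.

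The 20 genes that spread most over the libraries, taken by a rule fixed before the data were examined among genes with at least 50 CPM in some library, left out sex-linked, haemoglobin and mitochondrial genes. In libraries 1 to 4, Ramp2, a partner of the adrenomedullin receptor, stood at 64.1, 68.9, 4.38 and 6.29 CPM, Bex2 at 44.4, 56.7, 4.6 and 4.06 CPM, and the cyclin gene Ccnd2 at 153, 218, 25.7 and 19.5 CPM. Apoe, which encodes a lipid carrier, stood at 418, 383, 50.8 and 66 CPM, and Rarres2, which encodes chemerin, at 135, 87.8, 12.4 and 20.9 CPM. The intermediate filament genes Des and Nes were at 52.8, 55.5, 6.41 and 6.66 CPM and at 94.1, 107, 20.5 and 18 CPM. The heat shock gene Hspb1 was at 133, 76.6, 20 and 22.7 CPM and the creatine kinase gene Ckb at 214, 148, 36.7 and 38.9 CPM. Igfbp5 was at 53.4, 57.3, 9.44 and 11.4 CPM, Islr at 119, 109, 21 and 25.4 CPM, Cavin3 at 109, 86.4, 17.8 and 21.1 CPM, and C1qtnf6 at 64, 54.5, 11 and 14 CPM. Crip1 was at 77.9, 39.2, 7.82 and 12.2 CPM, Ndrg2 at 52.2, 23.4, 6.48 and 9.44 CPM, Fxyd1 at 53.9, 40.3, 6.99 and 8.52 CPM, and the retinoid-metabolising dehydrogenase gene Dhrs4 at 73.2, 73.8, 9.78 and 11.1 CPM. The other 3 had another order: the predicted gene Gm8797 at 6.92, 6.74, 56.5 and 59.8 CPM, the carbonyl reductase gene Cbr3 at 26.8, 10.3, 59.7 and 35.3 CPM, and the monooxygenase gene Fmo2 at 99.7, 23.4, 98.1 and 152 CPM. Among 3920 genes that passed the minimum, the highest library was over 2 times the lowest for 275 and over 4 times for 40, and the median gene spanned 1.26 times. These levels pool mesenchymal classes whose shares differed between libraries. Within a class some genes spread less. Nes spanned 1.06 times in pericyte-like cells, against 5.96 times pooled, and Ckb 1.6 times in cluster 10, against 5.84 times. Others spread more. Ccnd2 spanned 1.63 times in pericyte-like cells but 23.7 times in distal-scoring clusters, against 11.2 times pooled. Des spanned 34 times in distal-scoring clusters, against 8.66 times pooled.

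**Figure D4:**
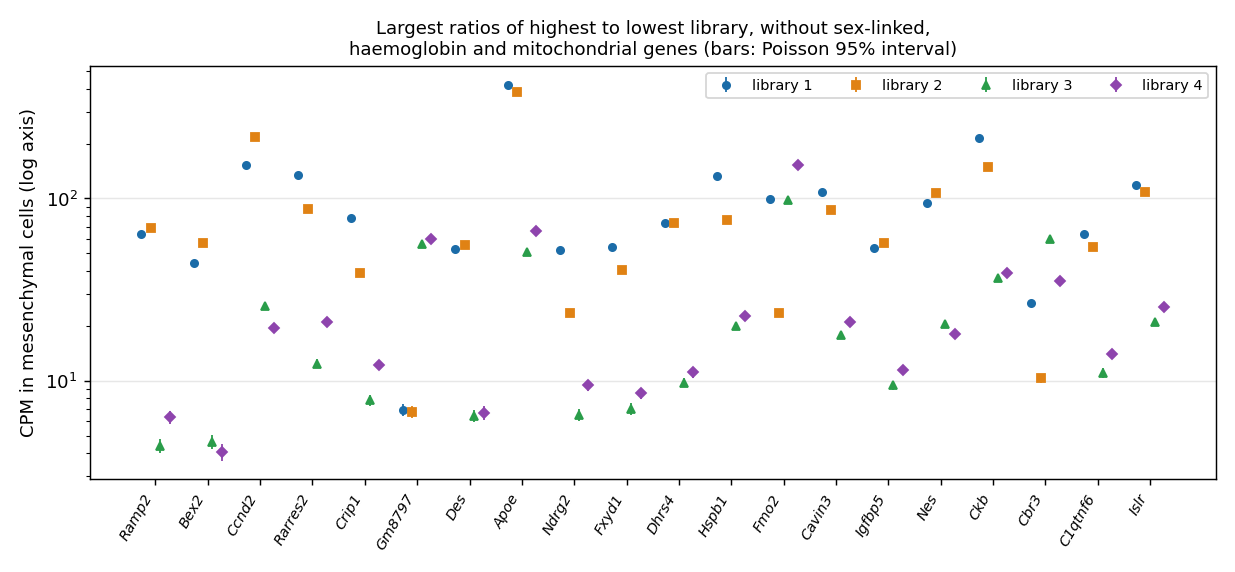
CPM over all mesenchymal cells (vertical log axis) of the 20 genes with the largest ratio of the highest to the lowest library once sex-linked, haemoglobin and mitochondrial genes were left out, 1 point per library, with exact 95% Poisson intervals. Ramp2 spans from 4.38 to 68.9 CPM and Apoe from 50.8 to 418 CPM.

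The share of cells counted as holding mitotic transcripts depended on the number of UMIs required. With each cell thinned to 2000 UMIs, 76.8% (75.8 to 77.7), 81.5% (80.6 to 82.4), 93.1% (92.5 to 93.6) and 92.0% (91.3 to 92.7) of mesenchymal cells in libraries 1 to 4 held at least 2 UMIs of the G2 and M phase list; 6, 8, 14 and 12 shallower cells were left out, and the unthinned shares were 99.3% to 99.9%. This measure was close to saturation, and immune-like cells gave 60.6%, 79.2%, 78.5% and 66.0%. The list also made up 6240, 7060, 8020 and 6730 CPM of the free RNA in barcodes under 100 UMIs, near the 6650, 7280, 7860 and 7530 CPM of the mesenchymal cells, so cells with few such UMIs cannot be told from background. At 10 UMIs, a limit chosen after seeing the data, the shares were 29.7% (28.7 to 30.7), 37.0% (36.0 to 38.1), 41.0% (39.9 to 42.2) and 38.8% (37.5 to 40.1). The share of free RNA in each cell was not estimated. Barcodes under 100 UMIs held 3.38%, 3.23%, 5.25% and 3.27% of the UMIs of libraries 1 to 4. If free RNA made up a similarly small share of a cell, it would account for few of the 10 UMIs. How far background adds to these shares was not tested. The summed S phase list was at 2900, 3470, 3960 and 3710 CPM. At 10 UMIs the share in cluster 10 was 7.68%, 8.97%, 20.5% and 14.4%, against 43.9%, 48.4%, 37.5% and 34.4% in pericyte-like cells. It was 24.6%, 28.9%, 18.5% and 15.8% in contractile-scoring clusters and 32.4%, 41.8%, 43.8% and 41.7% in distal-scoring clusters. The order of the libraries thus differed between classes. Clusters led by mitotic or histone genes counted as distal-scoring, and how far this sets the differences between classes was not tested.

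By its sex-linked genes, library 2 held RNA of female and libraries 1, 3 and 4 of male embryos. Xist, the RNA that silences an X chromosome, was at 1160 CPM in library 2 and at 0.0732, 0.0186 and 0.0699 CPM in libraries 1, 3 and 4. The Y-linked Ddx3y was at 71.3, 61 and 62.9 CPM in libraries 1, 3 and 4 and at 0.00882 CPM in library 2. Over genes, the chi-square of the counts of any pair of libraries was at least 12.6 per gene. Among their cells, libraries 1 and 2 shared 22 barcode sequences against 9.5 expected by chance, libraries 2 and 3 shared 22 against 8.8, libraries 2 and 4 shared 18 against 7.4, and the other pairs 8 to 13 against 7.0 to 8.9.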

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

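No paired analysis was possible because the columns carry no replicate number, and no setting of the control against knockout comparison was run. The 10-UMI cycling limit, the removal of the highest 6% of doublet scores and the contractile-scoring set and cluster 10 (proximal-scoring) as sets were chosen after seeing the data. Of 158 alternative values of the main results, 94 stayed within the interval or within 1.5 times the count, and 64 did not. The cause was not tested. Keeping doublets added only 11 cells, yet it moved the median mesenchymal share from 95.1% to 82.7% and left no proximal-scoring cluster. The clusters were thus sensitive to a very small change of the cells.

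The median mesenchymal share of 95.1% moved to 94.3% with a minimum of 500 UMIs, 96.8% with 3000 UMIs, 84.5% with a mitochondrial limit of 5%, 82.7% with doublets kept, 83.5% at resolution 2, 80.8% with each library clustered alone, 78.1% by the highest marker score per cell and 83.5% without the highest 6% of doublet scores; without each library in turn it ran from 85.8% to 94.2%. In several of these settings unnamed clusters scored highest on the erythroid list (2656 cells with doublets kept, 2710 at resolution 2), while the 4 named other types together made up 1.45% to 2.26% of all cells in the settings that clustered libraries jointly; by the highest marker score per cell their medians were 5.22% mesothelial, 3.28% endothelial, 1.26% epithelial and 1.48% immune. The median pericyte-like share of 3.86% moved to 4.41% at resolution 0.5, 6.16% with each library alone, 7.1% by the highest marker score and 3.28% without the highest doublet scores, and ran from 3.81% to 5.86% with each library left out. Leaving out a library also changes which libraries enter these medians. The median Sin3a level of 28.8 CPM moved only with classes weighted equally, to 27.1 CPM. Its range over libraries did depend on the scaling, from 27.7 to 30.5 CPM in the main setting and from 26.4 to 32.0 CPM with TMM.

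With a CPM minimum of 10, the calls grew to 28 lower in distal interstitial fibroblast-like cells, 26 higher and 18 lower in smooth muscle-like cells, 19 and 43 in pericyte-like cells, 24 and 14 in contractile-scoring clusters and 31 lower in the proximal-scoring set. With a minimum of 200 they fell to 3 and 3, 3 and 3, 5 and 8, 4 and 3, and 10 and 4, since fewer genes pass. With 3000 UMIs per cell there were 20 higher and 5 lower in distal interstitial fibroblast-like cells, 30 and 70 in smooth muscle-like cells and 10 lower in the proximal-scoring set. Resolution 0.5 gave 0 and 2 in distal interstitial fibroblast-like cells. Resolution 2 gave 34 and 5 there, 25 lower in smooth muscle-like cells and 11 lower in the proximal-scoring set. With doublets kept, 2 were higher in distal interstitial fibroblast-like cells and no cluster scored highest on the proximal list. Without the highest doublet scores, 2 and 4 were called in distal interstitial fibroblast-like, 35 and 71 in smooth muscle-like cells, and 3 higher in the proximal-scoring set. Leaving out each library gave 8 to 31 higher and 9 to 11 lower in distal interstitial fibroblast-like cells, 12 to 21 and 9 to 12 in smooth muscle-like cells, 11 to 12 and 25 to 27 in pericyte-like cells, 11 to 18 and 7 to 9 in contractile-scoring clusters, and 16 to 24 and 20 to 34 in the proximal-scoring set. TMM scaling kept every count within 1.5 times.

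The cycling share of 86.8% became 75.7% at 3 UMIs, 37.9% at 10 UMIs, 68.6% with thinning to 1000 UMIs, 99.8% without thinning and 85.8% with doublets kept. The number of lists spanning at least 1.5 times, 8, was 6 with TMM scaling, 6 with classes weighted equally, 9 with 3000 UMIs and 9 by the median of log2 CPM. By that median the p53, S phase, WNT, retinoid and interferon lists passed and the matrix, lipid, neuronal and germline lists no longer did. With TMM scaling the matrix (1.42 times), PDGF, Notch and VEGF (1.43 times) and dissociation (1.39 times) lists fell short, and the S phase list (1.55 times) passed. With classes weighted equally those 3 fell short as well, at 1.38, 1.18 and 1.39 times, and the retinoid list passed at 1.53 times.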

Other observations

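The tests below were chosen after the result was seen, except the 3 on stray cells. By their values the libraries fell into 2 pairs, 1 with 2 and 3 with 4, to which no label gives a group. Over all mesenchymal cells, 13 genes differed over 2-fold between libraries 1 and 2 and 1 gene between libraries 3 and 4, against 216 between 1 and 3, 192 between 1 and 4, 173 between 2 and 3 and 168 between 2 and 4, among genes with at least 50 CPM in either library. Beyond the genes named by rule, the histone variant gene H2afj showed this in distal-scoring clusters, at 196, 169, 704 and 702 CPM in libraries 1 to 4, and in pericyte-like cells, at 133, 127, 503 and 490 CPM, but was at 324, 363, 383 and 313 CPM in immune-like cells.

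Among 278 genes over 2-fold apart between libraries in distal-scoring cells, those that also reached 50 CPM in another cell type were used to compare each library's deviation from the gene's mean between the types. The slope across genes was 0.75 (bootstrap 95% interval over genes, 0.68 to 0.82; 215 genes) in pericyte-like and 0.71 (0.64 to 0.79; 213 genes) in mesothelial-like cells, but 0.2 (0.13 to 0.3; 132 genes, under 0.5 of the set) in immune-like, 0.15 (0.061 to 0.25; 154 genes) in endothelial-like and 0.13 (0.023 to 0.24; 161 genes) in epithelial-like cells. The endothelial-like slope rests on 52, 25, 23 and 15 cells of libraries 1 to 4 and the epithelial-like slope on 25, 6, 13 and 16. The intervals resample genes only and cover neither the sampling of cells nor that of libraries. An effect on all RNA of a library would give a slope near 1 in immune-like cells, and a shift of cell makeup alone would give a slope near 0 in pericyte-like cells, so for the genes measured there neither accounts for the pattern by itself, nor does embryo sex, since 216 genes separate libraries 1 and 3, both male. Genotype, litter or a handling difference that spares other cell types may underlie it, and none of these was tested, because no cell is tied to a sample.

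A few cells of libraries 3 and 4, 149 and 210, lay in mesenchymal clusters to which their own library gave under 5% of the cells, as did 8 and 4 of libraries 1 and 2. Their resemblance to the libraries filling those clusters follows from how they were picked: in the strays of libraries 3 and 4, Lgals1 was at 1060 and 1030 CPM against 220 and 181 CPM in the other mesenchymal cells of the same libraries, Ramp2 at 39.4 and 43.7 against 3.74 and 5.1 CPM, and Sin3b at 154 and 155 against 220 and 231 CPM. Cells carried over from library 2 would bring its Xist, which was at 0 CPM in both sets of strays, and cells carried over from library 1 would bring its low Rpl29 of 230 CPM, whereas the strays had 991 and 1030 CPM. Doublets would hold more UMIs, but the strays had at most 0.839 times the median of the other cells. What these cells are stays open, and no biological explanation was tested, since no cell has a group.

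The ribosomal protein gene Rpl29, on chromosome 9, was at 230 CPM in library 1 and 1100, 1260 and 1280 CPM in libraries 2 to 4, and the glycolytic gene Pkm, also on chromosome 9, was at 409 CPM in library 2 and 123, 126 and 113 CPM in libraries 1, 3 and 4. The other genes apart in a single library over all mesenchymal cells lay on other chromosomes. Among them were Fmo2 on chromosome 1 (4.19 times from the nearest library), Hspa1a on chromosome 17 (2.23 times) and Crip2 on chromosome 12 (2.2 times). A shift of cell makeup would move Rpl29 and Pkm in few classes, but for both genes the library lay at least 2.01 times from the nearest other in each of the 4 mesenchymal sets. Variants carried along with the Sin3a locus could alter counts near it, and among 28 measured genes within 5 Mb 1, Pkm at 2.58 Mb, was apart in a single library over all mesenchymal cells. Rpl29 lies 49.4 Mb from Sin3a, outside that window, so a test within 5 Mb does not cover it. The first form of this test asked for genes apart in each of the 4 sets and found 0, which would argue against this source; it was replaced after that result was seen, because Pkm, though over the fold limit of 1.5 in each set, missed its further condition that the other 3 libraries span under 0.5 of the log2 gap, so the explanation is left open on a criterion chosen with its outcome known. Variants against the reference and reads shared with pseudogene copies cannot be weighed without the reads.

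In the free RNA, Sftpc, the surfactant protein C gene, made up 424, 14.9, 1430 and 147 CPM of the UMIs in barcodes under 100 UMIs in libraries 1 to 4, and the haemoglobin genes 303, 67.5, 588 and 756 CPM.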
